A study of Mus musculus with 30 samples.

How the data were processed

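The authors deposited gene-level estimated counts and a table of log2 CPM (read counts scaled to library size). Salmon 1.10.0 and the builds GRCm39 and mm39 are named in the submitters' processing notes, with no role or order given. How transcripts were summed to genes is not recorded there. Libraries were made from polyadenylated RNA, per the labels' protocols. The deposited estimated counts are unscaled reads per gene with a symbol and an Entrez identifier, per the file headers, and 40.8% of their values were not whole. The deposited log2 values are TMM-normalized log2 CPM by the authors, per the file headers, for 13087 genes, and served in 1 alternative. Replicate 5 of the non-adherent cells at 72 h was removed by the authors as an outlier, per the labels, and was not used here. The count table holds 0 mitochondrially encoded genes, and strand was not used in any step here.

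From the deposited estimated counts, rounded to whole numbers, 13008 of 39253 genes passed edgeR's filterByExpr (minimum count 10, minimum total 15), and 16580 genes were 0 in every library. TMM factors scaled the libraries. All 6 groups were fitted in 1 edgeR quasi-likelihood model (glmQLFit, robust) and tested with glmQLFTest, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The standard error is the absolute log2 fold change divided by the square root of the F statistic. CPM values use the same TMM factors, and log2 CPM a prior count of 2. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

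The comparisons were adherent 27HC-sEV against DMSO-sEV cells, non-adherent against adherent 27HC-sEV cells and non-adherent 27HC-sEV against DMSO-sEV cells, each at 48 and 72 h, then 72 against 48 h in each kind of cell, and the difference between times of the former pairs. The labels do not say whether replicates are separate cultures or vesicle batches, so the p-values measure only the spread between these libraries, which may be technical.

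Gene lists, 43 in number, were fixed by symbol, and the 39 with at least 5 tested genes were tested with camera (limma) at a preset correlation of 0.01, adjusted over the 39 lists of a comparison. They cover epithelial, mesenchymal, EMT transcription factor, stem cell, Wnt, TGF-beta and BMP, YAP, integrin, matrix, actin, G1/S, G2/M, p53, apoptosis, ATF4, endoplasmic reticulum stress, heat shock, cholesterol, LXR, fatty acid, estrogen, NRF2, hypoxia, interferon, NF-kappa B, immediate early, antigen presentation, lysosome, oxidative phosphorylation, mitochondrially encoded, ribosomal protein, MYC, histone, drug efflux, senescence, luminal, basal, neutrophil, macrophage, lymphocyte, fibroblast, endothelial, and erythroid and platelet genes. A list median and mean are over its tested genes, whether or not they passed. Alternatives were camera with a correlation estimated per list, and fry. Fry's directional p tests whether a list's genes move on balance one way, its mixed p whether they change in either direction, and neither compares the list with other genes. Fry called 26, 34, 32 and 17 lists in the directional test and 39, 39, 37 and 37 in the mixed test, for adherent against DMSO-sEV cells at 48 and 72 h and non-adherent against adherent cells at 48 and 72 h.

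The comparisons, the tests, the lists, the rule for naming genes and most alternatives were fixed before the data were examined. In the comparisons of adherent with DMSO-sEV cells and of non-adherent with adherent cells, the rule names the 6 largest increases and 6 largest decreases among genes with adjusted p under 0.05, mean log2 CPM of at least 3 and fully separated libraries, leaving out clone and predicted-gene names. It adds, from each of the 10 called lists with the smallest camera p, the 2 genes with the smallest p in the called direction, and Cdh1, Epcam, Cdh2, Vim, Fn1, Snai1, Snai2, Zeb1, Zeb2 and Cd44, of which Cdh2 and Snai2 were too low to test. In the other pairs it names the 4 largest increases and 4 largest decreases, and for differences between times the 3 of each with the smallest adjusted p. Some genes chosen by these rules are not reported here, nor counted among named genes that stood apart or differed between times.

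These alternatives were unrounded counts, RLE and upper-quartile factors, DESeq2, limma-voom, limma-trend on the deposited log2 CPM, 1 CPM in every library of a group, no filter except 1 count, a replicate block, a fit of only the groups compared, and leaving out each library. Added after the data were seen were length and GC offsets, DMSO replicates 1 to 3 alone, and DMSO replicates 4 and 5 alone. The offsets are per library, natural splines of 4 degrees of freedom each in log2 transcript length and in GC content with their products, fitted to 10637 genes with mean log2 CPM of at least 1. Length and GC come from the longest GENCODE M21 transcript per symbol, on GRCm38, matched by symbol for 12225 of 13008 genes (93.98%). That build differs from the authors', so no coordinates are given. The offsets are 1 definition among several, and can also remove biology that goes with length or GC. Lists were tested again with offsets for 38 lists, since histone genes had too few lengths.

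On simulated counts with known changes, 94.9, 90.9, 96 and 91.8% of genes changed by 1 log2 unit were recovered in the 4 comparisons in the order above, and 73.5, 75.3, 71.4 and 71.7% of those changed by 0.5. False calls were 5.14, 1.81, 2.92 and 6.94% of calls, over 12807, 12806, 12791 and 12824 genes. A length trend, without a GC trend and the same in every adherent library at 72 h, was then added to simulated counts. For adherent against DMSO-sEV cells at 72 h, over 12080 genes, 4370 unchanged genes were called without offsets and 20 with them. With offsets 87.5% of changed genes were recovered. The offsets fit that same length, so the simulation does not test them on a trend that differs between libraries. Median shifts between TMM, RLE and upper-quartile scaling stayed under 0.05 log2 units.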

Results

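RNA was sequenced from 4T1 cells, a mouse mammary carcinoma line, after 48 or 72 h in culture with small extracellular vesicles (sEVs) from primary neutrophils of BALB/c mice. The neutrophils had been exposed for 48 h to vehicle (DMSO) or to 10 µM 27-hydroxycholesterol (27HC), an oxysterol made from cholesterol. Cells under vesicles of 27HC-exposed neutrophils (27HC-sEVs) were collected as an adherent and a non-adherent fraction, and cells under vesicles of vehicle-exposed neutrophils (DMSO-sEVs) as adherent cells. Each of the 6 groups held 5 libraries except the non-adherent cells at 72 h, with 4. No cells without vesicles were included. Total estimated counts ran from 18.8 to 31.4 M reads per library, and group means from 20.9 M (SD 2.68, n = 4) to 23.7 M (SD 2.9, n = 5). Of 39253 genes in the count table, 13008 were tested in all comparisons. The first principal component held 49.6% of the variance and ordered the groups from DMSO-sEV cells at 72 h (mean -49.7, SD 10.7, n = 5) through adherent 27HC-sEV cells to non-adherent cells at 72 h (mean 40.6, SD 1.9, n = 4).

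**Figure D1:**
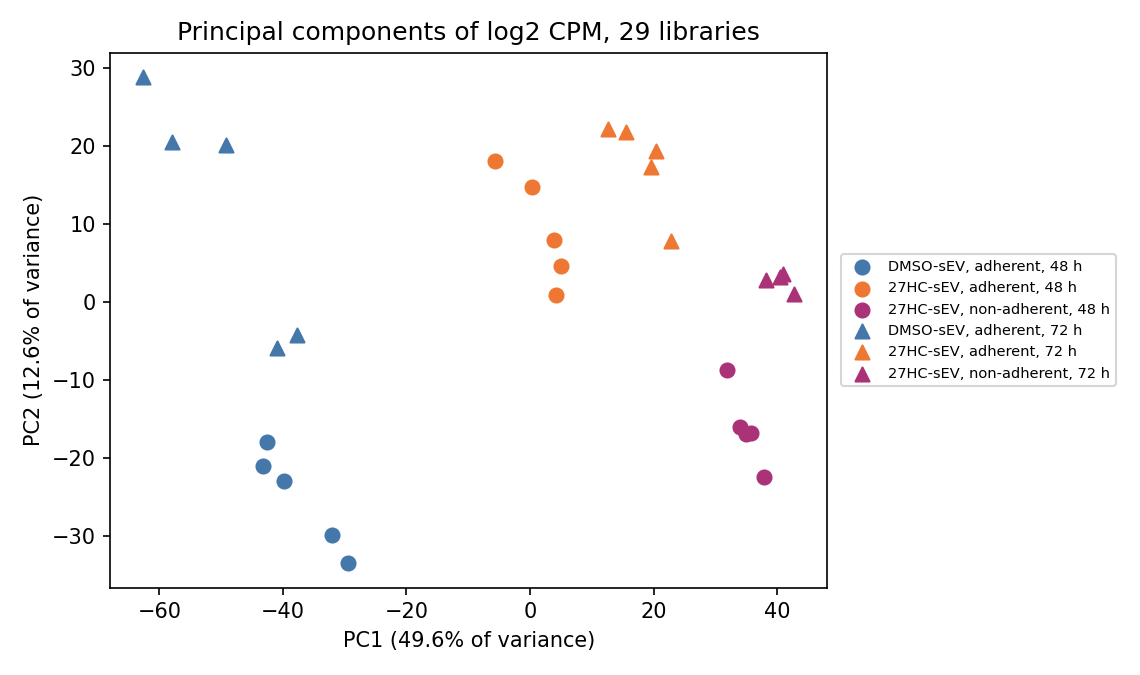
First against second principal component of log2 CPM, the read counts scaled to library size (unitless scores), one point per library, coloured by group. The first component places all 10 libraries of DMSO-sEV cells below the 19 libraries of 27HC-sEV cells and carries 49.6% of the variance, the second 12.6%.

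The comparison of adherent 27HC-sEV cells with DMSO-sEV cells at 48 h asks what the oxysterol exposure of the neutrophils changes, through their vesicles, in tumour cells that stay attached, with transition from epithelial to mesenchymal state (EMT) and stemness named as the study's subjects. The cholesterol pathway fell furthest. Hmgcs1 (Entrez 208715), the synthase that starts the mevalonate pathway, went from 613 CPM (SD 23.2, n = 5) to 67.2 CPM (SD 2.27, n = 5), a log2 fold change of -3.19 (SE 0.048, edgeR adjusted p = 4.2e-28). Genes of the stress response to amino acid shortage and misfolded protein rose, with Ddit3 (Entrez 13198), a transcription factor of that response, up 9.78-fold (log2 fold change 3.29, SE 0.13, adjusted p = 1.82e-18). Among 13008 genes, 2772 rose and 2955 fell, 443 and 221 of them by at least 2-fold.

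Largest changes, here and below, are among genes with a mean log2 CPM of at least 3 and fully separated libraries. The 6 largest decreases were all in sterol synthesis. Beside Hmgcs1, log2 fold changes were -3.48 (SE 0.096) for Lss, which makes lanosterol, -3.39 (SE 0.12) for the isomerase Idi1 (Entrez 319554), -3.27 (SE 0.15) for the sterol demethylase Cyp51, -3.12 (SE 0.085) for Hsd17b7 and -2.90 (SE 0.068) for the farnesyl diphosphate synthase Fdps. Of 28 tested genes for cholesterol biosynthesis, 27 fell and 1 rose, with the same counts adjusted over the list alone (median -2.33, camera adjusted p = 1.57e-136). The riser was Ggps1 (0.21), which leads to a branch outside sterols. Of the lists below and in the other comparisons, those given without a count adjusted over the list alone had that count unchanged. Names of members that moved against their list were chosen after their values were seen, here and in the other comparisons. Of 33 genes for fatty acid synthesis and oxidation 15 fell and 6 rose, also over the list alone (median -0.13, camera adjusted p = 0.000555, adjusted p = 0.113 with an estimated correlation). The 18 targets of the liver X receptor (LXR), which senses oxysterols, went both ways: 5 rose and 5 fell, and their median of 0, mean of 0.17 and downward test (camera adjusted p = 0.468) differed in sign. The 5 risers, chosen after their values were seen, were the sterol exporters Abcg1 (4.15) and Abca1 (3.29), Npc1, Plin2 and Nr1h2. The 5 that fell were the desaturases Scd1 (-2.12) and Scd2 (-1.72), Lpcat3, Srebf1 and Pltp. Abca1 and Abcg1 were low, at 0.0369 CPM (SD 0.0507, n = 5) and 0.239 CPM (SD 0.164, n = 5) in DMSO-sEV cells.

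The 6 largest increases were Prl2c3, Ddit3, Fam171b, Atf3, Gpnmb and Dio2. Prl2c3 (Entrez 18812), of the prolactin family, rose from 1.89 CPM (SD 0.412, n = 5) to 30.3 CPM (SD 5.1, n = 5), 15.9-fold (adjusted p = 7.76e-17). Its near-identical neighbours Prl2c2 and Prl2c5 can share its reads, so the value is uncertain between them. Fam171b rose 7.6-fold, the stress-induced transcription factor Atf3 6.39-fold, the lysosomal glycoprotein Gpnmb 6.16-fold and the thyroid hormone deiodinase Dio2 5.71-fold. By the rule that chose these 12 genes, every library of one group lay beyond every library of the other. Of 39 genes of the integrated stress response driven by ATF4, 33 rose and 1 fell, 34 and 1 adjusted over the list alone (median 0.85, camera adjusted p = 1.5e-43). Ddit3 was joined by the pseudokinase Trib3 (log2 fold change 2.26, SE 0.083), and the member that fell was Cth. Of 34 genes for endoplasmic reticulum stress 11 rose and 2 fell, Creb3l2 and Edem1 (median 0.09, camera adjusted p = 0.00159, adjusted p = 0.602 with an estimated correlation). That call depended on the DMSO-sEV libraries: with replicates 4 and 5 alone 20 rose and 1 fell (camera adjusted p = 1.03e-07), and with replicates 1 to 3 alone 10 rose and 13 fell without a call (median -0.019, camera adjusted p = 0.178). Of 38 lysosome and autophagy genes 26 rose and 1 fell, Gusb, and 28 and 1 adjusted over the list alone (median 0.48, camera adjusted p = 1.9e-09, adjusted p = 0.155 with an estimated correlation). Sqstm1, the autophagy receptor, rose 2.97-fold and the proton pump subunit Atp6v1d by 0.57 (SE 0.049).

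Inflammatory and early-response genes rose. Of 38 NF-kappa B targets and cytokines 25 rose and 3 fell (Csf1, Vcam1 and Rel), 25 and 4 adjusted over the list alone (median 0.60, camera adjusted p = 4.53e-12). Nfkbia, the inhibitor induced by NF-kappa B, rose by 0.86 (SE 0.042) and Traf1 by 0.99 (SE 0.051). Of 35 immediate early genes 22 rose and 9 fell (22 and 11 over the list alone, median 0.43), among them the phosphatase Dusp1 (2.00, SE 0.105). Of 39 hypoxia and glycolysis genes 21 rose and 6 fell (23 and 7 over the list alone, median 0.34), with Ndrg1 up 4.1-fold and the Myc antagonist Mxi1 up by 0.88 (SE 0.046). The 32 p53 targets divided evenly, 12 up and 12 down (13 and 13 over the list alone, median 0.10, camera adjusted p = 0.0191, or median -0.03, 0.0542 and no call with DMSO replicates 4 and 5 alone). Of 40 interferon-stimulated genes 15 rose and 4 fell, Psmb9, Irf1, Stat2 and Psmb8 (median 0.24, camera adjusted p = 0.0817).

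Proliferation genes fell. Of 40 genes for G1/S and DNA replication 32 fell and 2 rose, Gins3 and Cdt1, and 35 and 2 adjusted over the list alone (median -0.39, camera adjusted p = 1.35e-13). The ribonucleotide reductase subunit Rrm2 fell by 1.099 (SE 0.04) and the helicase subunit Mcm3 by 0.59 (SE 0.042). Of 40 G2/M genes 35 fell and 0 rose, 37 over the list alone (median -0.34, camera adjusted p = 3.19e-11), including the cyclin Ccna2 (-0.73, SE 0.045) and the kinesin Kif20a (-0.48, SE 0.044). Of 40 MYC target and ribosome biogenesis genes 27 fell and 3 rose (29 and 3 over the list alone), Polr1c, Odc1 and Myc itself (median -0.31, camera adjusted p = 1.83e-06, adjusted p = 0.0986 with an estimated correlation). Srm, for spermidine synthesis, fell by 0.72 (SE 0.053) and Bop1 by 0.62 (SE 0.047).

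The mesenchymal list fell at 48 h: 14 of 25 tested genes fell and 3 rose (Mmp3, Serpine2 and Pdgfra), 15 and 3 adjusted over the list alone (median -0.50, camera adjusted p = 3.11e-05, adjusted p = 0.201 with an estimated correlation). Vim, the mesenchymal filament gene, fell by 0.15 (SE 0.042, adjusted p = 0.00425), Snai1 by 0.48 (SE 0.102) and Zeb1 by 0.87 (SE 0.221) from a low 2.5 CPM (SD 0.152, n = 5). Cdh1, the epithelial cadherin, also fell, by 0.30 (SE 0.125, adjusted p = 0.0478), a call that was lost in 15 of 23 alternatives (adjusted p from 0.00407 to 0.878). Epcam (-0.03, SE 0.14), Fn1 (-0.08, SE 0.158), Zeb2 (0.08, SE 0.09) and Cd44 (-0.04, SE 0.109) did not pass. Of 39 epithelial genes 11 rose and 9 fell (11 and 10 over the list alone, median 0.06, camera adjusted p = 0.624). Of 14 EMT transcription factors 3 rose (Id2, Sox9 and Runx2) and 5 fell (Zeb1, Snai1, Id1, Foxc2 and Id3), with a median of -0.07, a mean of -0.02 and an upward test (camera adjusted p = 0.827). Of 24 stem cell associated genes 4 rose and 9 fell (5 and 10 over the list alone, median -0.17, camera adjusted p = 0.431). The risers were Klf4, Cd24a, Myc and Abcb1b.

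Genes for attachment and contractility fell with the mesenchymal list. Of 23 YAP and TEAD targets 15 fell and 1 rose, Nt5e (15 and 2 over the list alone, median -0.46, camera adjusted p = 6.06e-07). Ccn2, the matricellular growth factor read as a YAP target, went from 509 CPM (SD 65.2, n = 5) to 119 CPM (SD 7.28, n = 5), down 4.29-fold, and the kinase Nuak2 fell by 1.55 (SE 0.071). Integrin and focal adhesion genes fell in 21 of 36 and rose in 1, Itga8 (22 and 1 over the list alone, median -0.25, camera adjusted p = 0.000555, adjusted p = 0.36 with an estimated correlation). Actin and myosin genes fell in 25 of 35 (26 over the list alone, median -0.24, camera adjusted p = 0.0008, adjusted p = 0.156 with an estimated correlation), extracellular matrix genes in 16 of 31 (median -0.42, camera adjusted p = 0.00518, adjusted p = 0.602 with an estimated correlation), and TGF-beta and BMP pathway genes in 18 of 33 (20 over the list alone, median -0.19, camera adjusted p = 0.00616, adjusted p = 0.36 with an estimated correlation). Mammary basal genes fell in 9 of 13 (median -0.49, camera adjusted p = 0.0342), a call that ended with length and GC offsets (median -0.50, camera adjusted p = 0.0948), with DMSO replicates 4 and 5 alone (median -0.203, 0.22) and with an estimated correlation (adjusted p = 0.36). Of the 39 lists tested in this family 19 were called, and the calls for cholesterol biosynthesis, the ATF4 response, G1/S, G2/M, NF-kappa B, immediate early, YAP, hypoxia and p53 genes held with an estimated correlation. With length and GC offsets as well, those for NF-kappa B (adjusted p = 0.0677), YAP (0.0677), immediate early (0.0976) and p53 genes (0.272) did not. Their medians were then 0.562, -0.458, 0.444 and 0.016, the first 3 close to those without offsets.

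The remaining lists had no call at 48 h. Ribosomal protein genes rose in 11 and fell in 2 of 40 (7 and 2 over the list alone, camera adjusted p = 0.0817) and were called higher with offsets (0.00295, or 0.541 with an estimated correlation) and with DMSO replicates 4 and 5 alone (1.41e-05). They were not with replicates 1 to 3 (0.38). Oxidative phosphorylation genes fell in 11 of 39 (10 over the list alone, camera adjusted p = 0.0733) and were called lower with offsets (0.0056, or 0.541 with an estimated correlation) and with DMSO replicates 1 to 3 alone (0.000362). With replicates 4 and 5 their median was 0.057 (0.946). Of 36 NRF2 oxidative stress genes 12 rose and 13 fell (12 and 14 over the list alone, median -0.08, mean 0.15, upward test, camera adjusted p = 0.645). Of 35 apoptosis genes 8 rose and 9 fell (median -0.02, mean 0.17, upward test, camera adjusted p = 0.726). Heat shock genes rose in 11 and fell in 8 of 29 (11 and 9 over the list alone), drug efflux genes rose in 5 and fell in 5 of 22, senescence-associated secretion genes rose in 9 and fell in 6 of 22, and antigen presentation genes rose in 6 and fell in 6 of 20. The 5 efflux genes that rose were Mgst1, Mgst2, Akr1b3, Nqo1 and Abcb1b, and the 5 that fell Abcg2, Abcc3, Gsto1, Abcc5 and Abcc1. Lists for cells other than the tumour line had few tested members: 7 for neutrophils, of which Il1b and Lcn2 rose and Mmp9 and Itgb2 fell (3 and 2 over the list alone, median 0.65, mean 0.23, downward test, camera adjusted p = 0.431), 5 for macrophages, of which Mrc1, Cd68 and Csf1r rose (camera adjusted p = 0.177), and 5 for fibroblasts, of which Pdgfra rose and Postn fell (median 0.01, mean -0.21, camera adjusted p = 0.645). The lymphocyte (1 tested), endothelial (2), erythroid and platelet (2) and mitochondrially encoded (0) lists were too small to test.

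**Figure D2:**
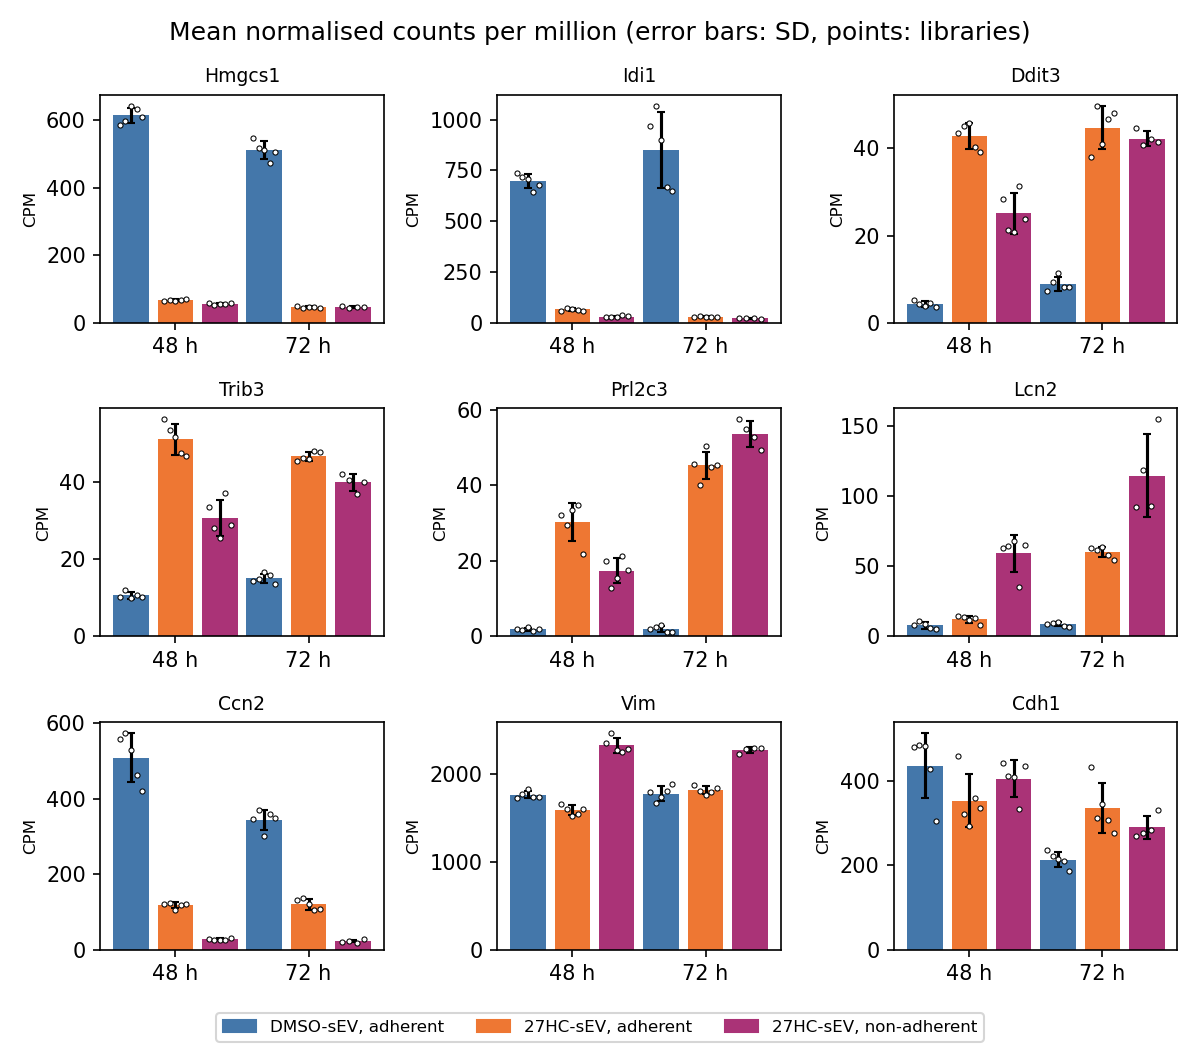
Mean CPM (bars from 0) with SD (error bars) and single libraries (points) of 9 genes in the 6 groups, n = 5 per group and 4 for non-adherent cells at 72 h. Hmgcs1 fell from 613 to 67.2 CPM at 48 h, and Ccn2 fell from 509 CPM in DMSO-sEV cells to 28.3 CPM in non-adherent cells.

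At 72 h the same comparison of attached cells asks whether the response lasts or changes with a further day of vesicle exposure. Idi1 fell 27.7-fold, from 851 CPM (SD 186, n = 5) to 30.7 CPM (SD 2.55, n = 5), a log2 fold change of -4.79 (SE 0.127, adjusted p = 3.85e-22). Prl2c3 rose 23.6-fold (log2 fold change 4.56, SE 0.179, adjusted p = 3.75e-18). Interferon-stimulated genes, with a median of 0.24 and no call at 48 h, fell: Ifit1 went from 17.3 CPM (SD 1.86, n = 5) to 4.04 CPM (SD 0.685, n = 5), down 4.26-fold. More genes passed, with 4160 up and 4340 down, 800 and 497 of them by at least 2-fold, and 73.7% of the calls held with length and GC offsets.

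Cholesterol genes were lower again. All 28 tested members fell, also over the list alone (median -2.39, camera adjusted p = 1.89e-86), with Cyp51 down 17.1-fold, the sterol-sensing Insig1 down 15.5-fold, Fdps down 11.6-fold, Lss down 11.2-fold and Hmgcs1 down 11-fold (log2 fold change -3.46, SE 0.049). Besides Prl2c3, the largest increases were Dio2 (13-fold), Gpnmb (8.53-fold), the ferrireductase Steap3 (7.23-fold), the siderophore-binding lipocalin Lcn2 (7.06-fold) and the cystine transporter Slc7a11 (6.71-fold, adjusted p = 3.79e-19). The ATF4 list rose in 32 of 39 genes and fell in 3 (Cth, Phgdh and Psat1), with a median of 0.82 (camera adjusted p = 3.52e-19), and the glycine transporter Slc6a9 rose by 2.51 (SE 0.106). Endoplasmic reticulum stress genes rose in 24 of 34 and fell in 2, Sec61b and Derl2, with 25 and 2 adjusted over the list alone (median 0.47, camera adjusted p = 3.42e-07, adjusted p = 0.352 with an estimated correlation). Their median was 0.291 with DMSO replicates 1 to 3 alone and 0.849 with 4 and 5. In that list Ddit3 rose 5.04-fold and Crebrf by 1.097 (SE 0.052). Lysosome and autophagy genes rose in 32 of 38 and fell in 3, Gabarapl2, Atg5 and Ctsh (33 and 3 over the list alone, median 0.54, camera adjusted p = 1.26e-07, adjusted p = 0.293 with an estimated correlation), including Sqstm1 (1.08, SE 0.058).

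Interferon-stimulated genes fell in 35 of 40 and rose in 0, with 36 down adjusted over the list alone (median -0.85, camera adjusted p = 8.21e-10), among them the RNA sensor Ifih1 (-1.17, SE 0.068). NF-kappa B targets and cytokines were higher again, 23 of 38 up and 4 down (Vcam1, Rel, Ccl5 and Nfkbie), 24 and 4 over the list alone (median 0.52, camera adjusted p = 8.88e-07, adjusted p = 0.101 with an estimated correlation). The neutrophil-attracting chemokine Cxcl5 rose by 2.14 (SE 0.122) and Il1a by 1.13 (SE 0.071). Immediate early genes rose in 21 of 35 and fell in 6 (median 0.37, camera adjusted p = 0.000162, adjusted p = 0.115 with an estimated correlation). G2/M genes fell in 38 of 40 (median -0.68, camera adjusted p = 8.94e-24), with Ccnb1 down by 0.94 (SE 0.044) and Ccna2 by 0.96 (SE 0.045). G1/S genes fell in 36 of 40 and rose in 2, Gins3 and Cdt1 (median -0.68, camera adjusted p = 1.48e-17), with Rrm2 down by 1.26 (SE 0.04) and Rrm1 by 0.91 (SE 0.044). The calls for cholesterol, G2/M, G1/S, interferon and ATF4 genes held with an estimated correlation, out of 21 lists called. With length and GC offsets as well the interferon call did not (adjusted p = 0.0941, median -0.764).

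EMT markers went both ways at 72 h. Cdh1 was higher by 0.65 (SE 0.125, adjusted p = 5.66e-05), opposite to 48 h, and the mesenchymal Fn1 by 1.27 (SE 0.161, adjusted p = 9.14e-08), or 0.754 with offsets. With time both fell in DMSO-sEV cells (436 to 214 and 2260 to 1080 CPM), against 353 to 335 and 2140 to 2630 CPM in adherent 27HC-sEV cells. The stem cell marker Cd44 rose by 0.49 (SE 0.109, adjusted p = 0.00027), Zeb2 by 0.33 (SE 0.089, adjusted p = 0.00201) and Zeb1 fell by 1.34 (SE 0.243). The Zeb2 call was lost with DMSO replicates 4 and 5 alone (0.11, adjusted p = 0.118, from 9.84e-09 to 0.118 over the alternatives). Epcam (-0.15, SE 0.14), Vim (0.03, SE 0.042) and Snai1 (-0.15, SE 0.102) did not pass. Epcam was called lower with DMSO replicates 1 to 3 (-0.413) and higher with 4 and 5 (0.389). Vim passed with offsets (0.20, adjusted p = 0.00209, from 0.00209 to 0.905 over the alternatives). Of 24 stem cell associated genes 15 rose and 5 fell, Ly6a, Abcg2, Abcb1a, Hes1 and Bmi1 (median 0.43, camera adjusted p = 0.0212, adjusted p = 0.485 with an estimated correlation). Offsets ended that call (median 0.312, camera adjusted p = 0.0859), as did DMSO replicates 1 to 3 alone (median 0.326, 0.103). Of 39 epithelial genes 18 rose and 9 fell (median 0.22, camera adjusted p = 0.34), and of 25 mesenchymal genes 10 rose and 8 fell (median -0.16, mean -0.05, upward test, camera adjusted p = 0.937).

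Fold changes at 72 h followed transcript length across genes (Spearman 0.366 over 10637 genes, which are not independent replicates), against 0.056 at 48 h, and several lists moved with it. DMSO-sEV libraries divided in this, and the correlation at 72 h was 0.456 with their replicates 1 to 3 alone and 0.108 with replicates 4 and 5 alone. Extracellular matrix genes, mostly long, rose in 23 of 31 and fell in 1, Tnc (median 0.93, camera adjusted p = 4.44e-05, adjusted p = 0.354 with an estimated correlation), and their median was 0.44 with length and GC offsets. The laminin chains Lamb2 and Lama5 rose by 1.28 (SE 0.077) and 1.30 (SE 0.106), or by 0.827 and 0.604 with offsets. Nuclear genes for oxidative phosphorylation, mostly short, fell in 39 of 39 (median -0.59, camera adjusted p = 2.58e-06, adjusted p = 0.521 with an estimated correlation), with a median of -0.29 with offsets. The median was -0.83 with DMSO replicates 1 to 3 alone and -0.229 with 4 and 5. Atp5b fell by 0.54 (SE 0.073) and Ndufs1 by 0.33 (SE 0.044), or 0.093 with offsets. Ribosomal protein genes fell in 30 of 40, 31 over the list alone (median -0.39, camera adjusted p = 0.0296), and offsets left a median of -0.04 and no call (camera adjusted p = 0.636). The ribosomal call also ended with an estimated correlation (adjusted p = 0.76). Its direction depended on the DMSO libraries, with a median of -0.638 with replicates 1 to 3 alone and 0.131 with replicates 4 and 5 alone (camera adjusted p = 0.51).

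Smaller calls at 72 h were made for MYC targets (25 of 40 down and 3 up, median -0.26, camera adjusted p = 0.00111, adjusted p = 0.332 with an estimated correlation) and Wnt genes (16 of 27 up and 2 down, median 0.32, camera adjusted p = 0.00658, adjusted p = 0.354 with an estimated correlation, 0.115 and median 0.17 with length and GC offsets). Polyadenylated histone transcripts fell in 8 of 13 (median -0.63, camera adjusted p = 0.0131, adjusted p = 0.352 with an estimated correlation). Mammary luminal genes rose in 7 of 14 and fell in 3 (median 0.58, camera adjusted p = 0.0147, adjusted p = 0.309 with an estimated correlation) and hypoxia genes in 19 of 39, with 10 down (median 0.10, camera adjusted p = 0.0165, adjusted p = 0.352 with an estimated correlation). Estrogen receptor associated genes rose in 10 of 17 (11 over the list alone, median 0.60, camera adjusted p = 0.0296, adjusted p = 0.293 with an estimated correlation), although Esr1 itself was among 5 that fell, with Myb, Sgk3, Ccnd1 and Cited2. Actin and myosin genes fell in 21 of 35 and rose in 7 (median -0.29, camera adjusted p = 0.0296, adjusted p = 0.354 with an estimated correlation, 0.0611 and median -0.242 with offsets) and apoptosis genes in 20 of 35, with 7 up (median -0.25, camera adjusted p = 0.0386, adjusted p = 0.352 with an estimated correlation, 0.112 and median -0.20 with offsets). With DMSO replicates 1 to 3 alone the calls for actin, hypoxia and luminal genes ended (medians -0.295, 0.037 and 0.571, camera adjusted p = 0.151, 0.0673 and 0.0648). Replicates 4 and 5 alone ended those for Wnt, apoptosis, estrogen receptor and histone genes (medians 0.369, -0.078, 0.757 and -0.361, camera adjusted p = 0.102, 0.0594, 0.0594 and 0.0522). YAP targets, called at 48 h, had 5 up and 6 down of 23 (median -0.03, camera adjusted p = 0.154) and were called lower with offsets (median -0.33, camera adjusted p = 0.0104, adjusted p = 0.299 with an estimated correlation) and with DMSO replicates 4 and 5 alone (0.00215), but not with 1 to 3 (12 up and 5 down, median 0.166, 0.911).

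**Figure D3:**
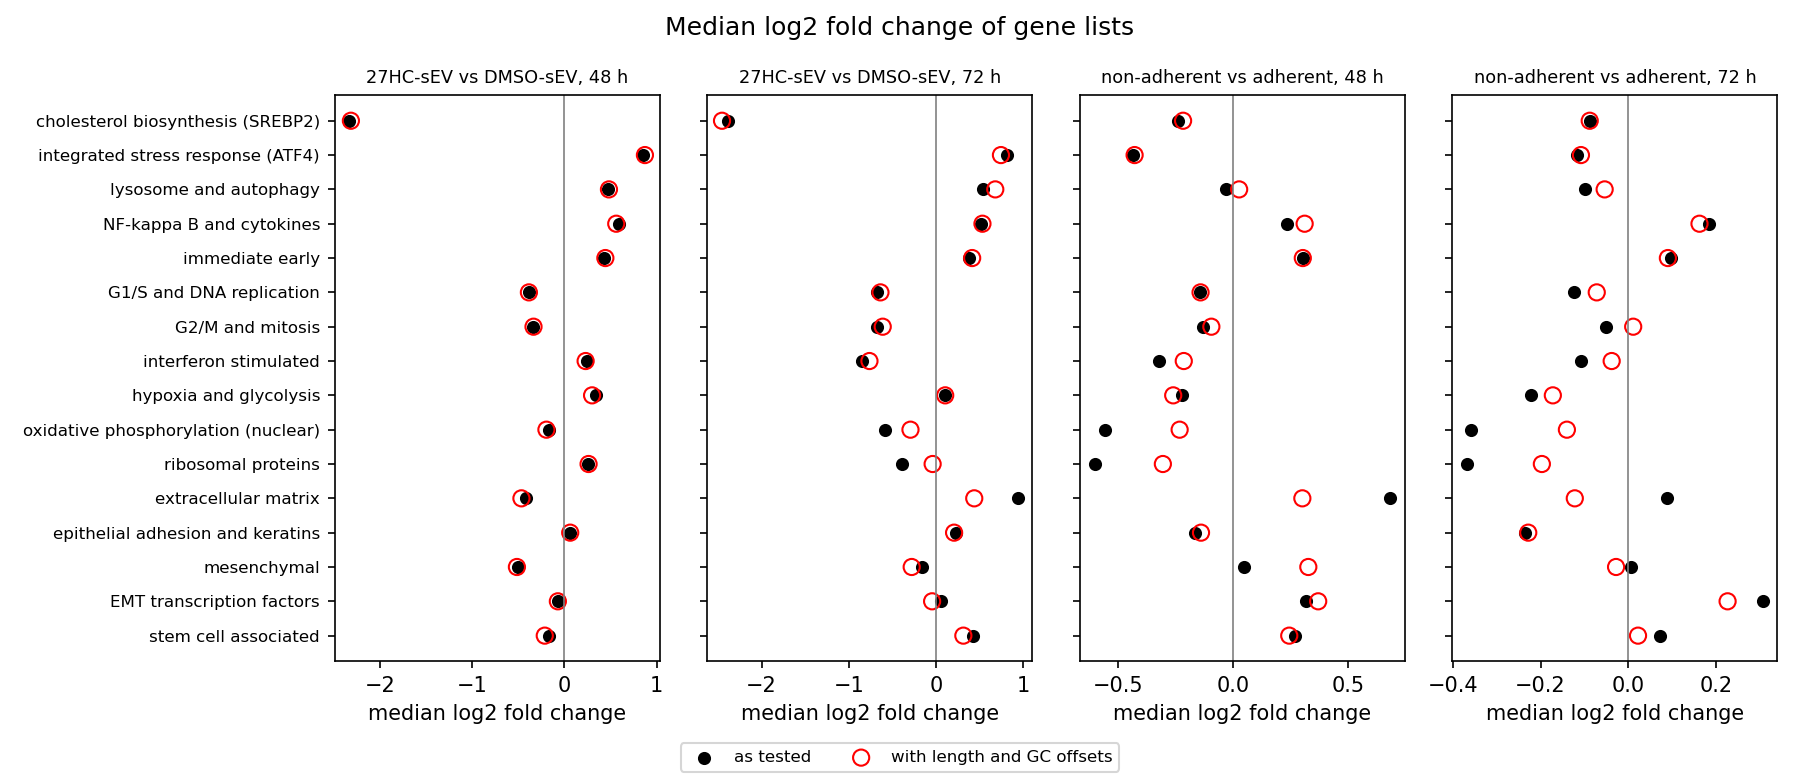
Median log2 fold change of 16 gene lists in 4 comparisons, as tested (black points) and with length and GC offsets (red rings). The cholesterol list lies at -2.33 and -2.39 in attached cells at 48 and 72 h, and the ribosomal protein list at -0.60 in non-adherent against adherent cells at 48 h, or -0.31 with offsets.

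Non-adherent against adherent cells under 27HC-sEVs at 48 h asks what distinguishes the cells that lost attachment. Lcn2 went from 12.3 CPM (SD 2.48, n = 5) to 59.3 CPM (SD 13.5, n = 5), up 4.81-fold (log2 fold change 2.27, SE 0.183, adjusted p = 1.32e-10). Ccn2 fell 4.19-fold further, from 119 CPM (SD 7.28, n = 5) to 28.3 CPM (SD 2.4, n = 5) (log2 fold change -2.07, SE 0.096, adjusted p = 5.11e-15). Vim rose 1.46-fold (SE 0.042 log2 units, adjusted p = 4.5e-11). In all, 3340 genes rose and 3693 fell, with 328 and 150 of them by at least 2-fold. Of the calls, 58.91% held in the same direction with length and GC offsets.

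After Lcn2, the largest increases were the endocytic receptor Lrp1 (3.8-fold, log2 fold change 1.925, or 1.083 with length and GC offsets, then the smallest of these 6), the transporter Abcc3 (3.78-fold), the prostaglandin E synthase Ptges (3.21-fold), the hedgehog-binding Hhip (3.19-fold) and Nptx1 (3.19-fold). After Ccn2, the largest decreases were Fgfbp1, which releases stored fibroblast growth factors (4.13-fold), the matrix protein Postn (3.63-fold), Serpinb5 (3-fold), the cathepsin Ctsw (2.93-fold) and Mal (2.79-fold). Separation of all libraries was again a condition for choosing these 12 genes.

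EMT transcription factors rose in 10 of 14 and fell in 0, with 10 and 1 adjusted over the list alone (median 0.32, camera adjusted p = 0.00189, adjusted p = 0.167 with an estimated correlation). Zeb2 rose by 0.49 (SE 0.089, adjusted p = 6.2e-05) and Snai1 by 0.28 (SE 0.103, adjusted p = 0.0255, from 0.00641 to 0.0658 over the alternatives), while Zeb1, at 0.942 CPM (SD 0.444, n = 5) in non-adherent cells, did not pass (-0.55, SE 0.244, adjusted p = 0.0599, from 0.00411 to 0.161 over the alternatives). The mesenchymal list rose in 12 of 25 genes and fell in 5 (among them Postn, Sparc, Cnn2 and Tpm1), 12 and 6 over the list alone (median 0.05, camera adjusted p = 0.0433). That call ended with length and GC offsets, where the median was larger (0.327, camera adjusted p = 0.0541), and with an estimated correlation (adjusted p = 0.478). Fn1 rose by 0.89 (SE 0.16, adjusted p = 5.99e-05), or by 0.46 with offsets, and the proteinase inhibitor Serpine2 by 1.33 (SE 0.132). Epithelial genes fell in 15 of 39 and rose in 2, Spint1 and Dsp (median -0.17, camera adjusted p = 0.000324, adjusted p = 0.247 with an estimated correlation), but Cdh1 (0.20, SE 0.125) and Epcam (-0.17, SE 0.14) did not pass. Stem cell associated genes rose in 14 of 24 and fell in 3, Abcg2, Procr and Myc (median 0.27, camera adjusted p = 0.000208, adjusted p = 0.247 with an estimated correlation). Among them Cd44 rose by 0.59 (SE 0.109, adjusted p = 7.78e-05), the receptor Lgr6 by 1.38 (SE 0.098) and the integrin Itgb3 by 1.12 (SE 0.108).

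Genes of the ATF4 response, raised in attached cells, were lower in non-adherent cells: 30 of 39 fell and 3 rose (Cebpb, Slc38a2 and Slc7a1), 31 and 3 over the list alone (median -0.44, camera adjusted p = 3.5e-14, adjusted p = 0.128 with an estimated correlation). The asparagine synthetase Asns fell by 0.92 (SE 0.057) and Ddit4 by 0.63 (SE 0.05). Hypoxia and glycolysis genes fell in 22 of 39 and rose in 6 (22 and 7 over the list alone, median -0.22, camera adjusted p = 3.02e-06, adjusted p = 0.128 with an estimated correlation), among them the glycolytic enzymes Pgk1 (-0.95, SE 0.078) and Ldha (-0.80, SE 0.079). With length and GC offsets the calls of the ATF4, hypoxia and neutrophil marker lists held with an estimated correlation (adjusted p = 0.0128, 0.0108 and 0.0108). As counted without offsets, none of the 23 calls of this comparison held with an estimated correlation. Inflammatory genes rose further: 21 of 38 NF-kappa B targets and cytokines rose and 5 fell (Ccl5, Il1b, Ptgs2, Cxcl16 and Nfkbib), 21 and 7 over the list alone (median 0.23, camera adjusted p = 4.61e-06, adjusted p = 0.167 with an estimated correlation). The neutrophil growth factor Csf3 rose by 1.44 (SE 0.109) and Tnfaip2 by 0.80 (SE 0.052). Interferon-stimulated genes fell in 22 of 40 and rose in 0 (median -0.32, camera adjusted p = 0.000324, adjusted p = 0.167 with an estimated correlation).

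Transcript length ran through this comparison too (Spearman 0.496 across genes, 0.391 to 0.565 for single non-adherent libraries at 48 h). Ribosomal protein genes fell in 40 of 40 (median -0.60, camera adjusted p = 6.49e-11, adjusted p = 0.322 with an estimated correlation), with a median of -0.31 with length and GC offsets. Rpl8 fell by 0.57 (SE 0.093), or 0.304 with offsets. Rps2 fell by 0.41 (SE 0.068), and by 0.12 without passing when offsets were used (adjusted p = 0.0663, with a range of 7.26e-09 to 0.0663 over all alternatives). Oxidative phosphorylation genes fell in 38 of 39 (median -0.56, camera adjusted p = 4.37e-10, adjusted p = 0.322 with an estimated correlation, median -0.23 with offsets), led by Uqcrq (-1.17, SE 0.173) and including Atp5b (-0.46, SE 0.073, or -0.264 with offsets). Extracellular matrix genes rose in 20 of 31 and fell in 0 (median 0.68, camera adjusted p = 3.3e-07, adjusted p = 0.247 with an estimated correlation, median 0.30 with offsets), such as Lama5 (1.22, SE 0.105) and the collagen Col5a1 (1.15, SE 0.101), or 0.49 and 0.65 with offsets. Integrin and focal adhesion genes rose in 19 of 36 and fell in 4, Itgb6, Ilk, Cav1 and Lims1 (median 0.31, camera adjusted p = 0.00129, adjusted p = 0.326 with an estimated correlation), and offsets ended that call (median 0.04, camera adjusted p = 0.492).

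Growth-factor lists rose. TGF-beta and BMP pathway genes rose in 19 of 33 and fell in 4, among them Ccn2, Fst and Tgfb2 (median 0.17, camera adjusted p = 0.000208, adjusted p = 0.247 with an estimated correlation), with Ltbp3, which stores latent TGF-beta, up by 1.23 (SE 0.086) and Bmp7 up by 0.94 (SE 0.078). Wnt genes rose in 15 of 27 and fell in 4, Wnt11, Wnt7a, Wnt10a and Myc (16 and 4 over the list alone, median 0.33, camera adjusted p = 0.000423, adjusted p = 0.247 with an estimated correlation). Senescence-associated secretion genes rose in 13 of 22 and fell in 4, among them Igfbp7, Mmp12 and Cdkn1b (14 and 4 over the list alone, median 0.42, camera adjusted p = 5.96e-05, adjusted p = 0.247 with an estimated correlation), including the chromatin protein Hmga1 (0.66, SE 0.044). Immediate early genes rose in 20 of 35 and fell in 5 (median 0.30, camera adjusted p = 0.000368, adjusted p = 0.167 with an estimated correlation) and luminal genes in 6 of 14, with 1 down (median 0.23, camera adjusted p = 0.0214, adjusted p = 0.247 with an estimated correlation). Of 7 neutrophil markers 4 rose (Lcn2, Itgb2, Mmp9 and Padi4) and Il1b fell (median 0.48, camera adjusted p = 0.00246, adjusted p = 0.128 with an estimated correlation).

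Growth and sterol lists fell further. MYC targets fell in 29 of 40 and rose in 1, Polr1a (30 and 1 over the list alone, median -0.21, camera adjusted p = 5.58e-06, adjusted p = 0.167 with an estimated correlation), such as Wdr12 (-0.66, SE 0.083). Cholesterol genes fell in 14 of 28 and rose in 2, among them Dhcr7 (median -0.24, camera adjusted p = 0.000624, adjusted p = 0.322 with an estimated correlation). Heat shock genes fell in 20 of 29 (median -0.19, camera adjusted p = 0.00303, adjusted p = 0.317 with an estimated correlation) and G1/S genes in 22 of 40 (24 over the list alone, median -0.14, camera adjusted p = 0.00761, adjusted p = 0.272 with an estimated correlation). G2/M genes fell in 23 of 40 and rose in 3, Mki67, Cenpf and Cenpe (median -0.13, camera adjusted p = 0.00227), a call that ended with offsets (median -0.095, camera adjusted p = 0.0636) and with an estimated correlation (adjusted p = 0.268). YAP targets divided into 8 up and 9 down of 23 (10 and 9 over the list alone, median -0.02, camera adjusted p = 0.0531), and were called lower with offsets (median -0.148, camera adjusted p = 0.00036, adjusted p = 0.189 with an estimated correlation). LXR targets rose in 9 of 18 and fell in 1, Plin2 (median 0.26, camera adjusted p = 0.0531).

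At 72 h the comparison of non-adherent (n = 4) with adherent cells (n = 5) asks whether the distinction persists. Mmp13, a collagenase, went from 44.3 CPM (SD 2.93, n = 5) to 190 CPM (SD 62.2, n = 4), up 4.28-fold (log2 fold change 2.10, SE 0.181, adjusted p = 3.57e-09). Ccn2 again fell most, 5.17-fold, from 121 CPM (SD 14.4, n = 5) to 23.3 CPM (SD 3.57, n = 4) (adjusted p = 3.94e-15). Lcn2 rose 1.9-fold (log2 fold change 0.93, SE 0.175, adjusted p = 0.000629). Fewer genes passed than at 48 h, with 1915 up and 1662 down, and 132 and 51 of them by at least 2-fold. Without adherent replicate 2 these counts were 1125 and 910, without non-adherent replicate 1 1236 and 1012, and without replicate 3 1208 and 981. Without replicate 4, 925 genes fell. A fit of only the groups compared gave 2805 and 2923. With offsets 53.92% of the calls held.

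Beyond Mmp13 and Lcn2, the largest increases were the noncoding RNAs Rn7sk (2.21-fold) and Malat1 (1.8-fold), both nuclear, and Glis3 (1.78-fold) and Lrp1 (1.75-fold, log2 fold change 0.805, or 0.346 with offsets). Rn7sk carries no poly(A) tail as a mature transcript. Ctsw fell 3.25-fold, Fgfbp1 3.11-fold, Postn 2.88-fold and Mal 2.28-fold. Of 2957 genes called at both times here, 2941 had the same direction (1934 shared calls if independent). A length trend at both times can also align calls.

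EMT transcription factors rose in 7 of 14 and fell in 0, 9 and 0 adjusted over the list alone (median 0.31, camera adjusted p = 0.0078, adjusted p = 0.331 with an estimated correlation). They included Zeb2 (0.38, SE 0.093, adjusted p = 0.00492), Tcf3 (0.31, SE 0.064, or 0.145 with offsets) and Sox9 (0.40, SE 0.086). Vim rose by 0.32 (SE 0.044, adjusted p = 9.26e-06). Epithelial genes fell in 13 of 39 and rose in 0, 14 and 2 over the list alone (median -0.24, camera adjusted p = 6.04e-07, adjusted p = 0.331 with an estimated correlation), with the keratins Krt19 and Krt7 down by 0.67 (SE 0.07) and 0.47 (SE 0.05). Cdh1 (-0.21, SE 0.133), Epcam (-0.35, SE 0.149, adjusted p = 0.075, from 0.000535 to 0.181 over the alternatives), Fn1 (0.27, SE 0.168), Snai1 (0.05, SE 0.108), Zeb1 (-0.20, SE 0.299) and Cd44 (-0.04, SE 0.115) did not pass. Mesenchymal genes divided into 4 up (Mmp3, Col6a1, Vim and Pdgfra) and 5 down (among them Postn, Cnn2, Thbs1 and Sparc) of 25 (5 and 6 over the list alone), with a median of 0.01, a mean of -0.16 and a downward test (camera adjusted p = 0.251). Stem cell associated genes divided into 4 up (Notch1, Notch2, Lgr6 and Klf4) and 4 down (Abcg2, Procr, Itgb1 and Lgr4) of 24 (5 and 5 over the list alone, median 0.07, camera adjusted p = 0.749).

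Hypoxia and glycolysis genes fell in 21 of 39 and rose in 0, 21 and 3 adjusted over the list alone (median -0.22, camera adjusted p = 4.95e-08, adjusted p = 0.0908 with an estimated correlation). The carbonic anhydrase Car9 fell by 0.96 (SE 0.109) and the kinase Pdk1 by 0.50 (SE 0.058). YAP targets fell in 10 of 23 and rose in 2, Ptpn14 and Myof (11 and 6 over the list alone, median -0.19, camera adjusted p = 3.45e-05, adjusted p = 0.331 with an estimated correlation), with Gadd45b down by 0.79 (SE 0.077). ATF4 response genes fell in 13 of 39 and rose in 1, Cebpb (14 and 1 over the list alone, median -0.12, camera adjusted p = 0.000256, adjusted p = 0.646 with an estimated correlation), including the cystathionine lyase Cth (-0.67, SE 0.08) and Stc2 (-0.66, SE 0.106). G1/S genes fell in 13 of 40 and rose in 1, Uhrf1 (15 and 1 over the list alone, median -0.12, camera adjusted p = 0.0078, adjusted p = 0.623 with an estimated correlation). In that list Ccne1 fell by 0.48 (SE 0.1) and Rrm2 by 0.23 (SE 0.043), and Rrm2 did not pass with length and GC offsets (-0.06, adjusted p = 0.517, with a range of 3.54e-07 to 0.517 over all alternatives). NF-kappa B genes rose in 14 of 38 and fell in 3, Vcam1, Ptgs2 and Csf1 (18 and 6 over the list alone, median 0.18, camera adjusted p = 0.0101, adjusted p = 0.646 with an estimated correlation), such as Traf1 (0.32, SE 0.053) and Nfkbia (0.25, SE 0.044). Antigen presentation genes fell in 4 of 20 (Cd274, Psmb10, Cd74 and Psmb8) and rose in 1, Nlrc5 (5 and 1 over the list alone, median -0.25, camera adjusted p = 0.0127, adjusted p = 0.649 with an estimated correlation), where Psmb8 and Psmb10 fell by 0.41 (SE 0.094) and 0.47 (SE 0.111). Endoplasmic reticulum stress genes fell in 5 of 34 (Creb3, Ero1a, Sec61b, Herpud1 and Derl2) and rose in 2, Ern1 and Crebrf (4 and 1 over the list alone, median -0.21, camera adjusted p = 0.0352, adjusted p = 0.832 with an estimated correlation). As counted without offsets 11 lists were called, 0 with an estimated correlation. With length and GC offsets hypoxia (adjusted p = 0.00636), epithelial and YAP genes (each 0.0426) held with it, and neutrophil markers, not called without offsets (3 of 7 up, camera adjusted p = 0.0546), were called (0.0426).

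Length again ran through the fold changes (Spearman 0.446 across genes). Oxidative phosphorylation genes fell in 26 of 39, 37 over the list alone (median -0.36, camera adjusted p = 2.46e-09, adjusted p = 0.646 with an estimated correlation), and the median was -0.14 with offsets. Atp5b fell by 0.31 (0.18 with offsets), and Ndufs1 by 0.20 (SE 0.047), which did not pass with offsets (-0.05, adjusted p = 0.306, with a range of 0.000156 to 0.306 over all alternatives). Ribosomal protein genes fell in 22 of 40, 36 over the list alone (median -0.37, camera adjusted p = 2.22e-08, adjusted p = 0.649 with an estimated correlation, median -0.20 with offsets), such as Rps6 (-0.35, SE 0.085, or -0.221 with offsets) and Rplp1 (-0.54, SE 0.155). The extracellular matrix list, called higher at 48 h, was not called at 72 h (5 up and 2 down of 31, 4 and 2 over the list alone, median 0.09, camera adjusted p = 0.572) and turned lower with offsets (median -0.12, camera adjusted p = 0.0236, adjusted p = 0.715 with an estimated correlation). Its 5 risers were Dcn, Vcan, Hspg2, Lama5 and Col6a1.

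**Figure D4:**
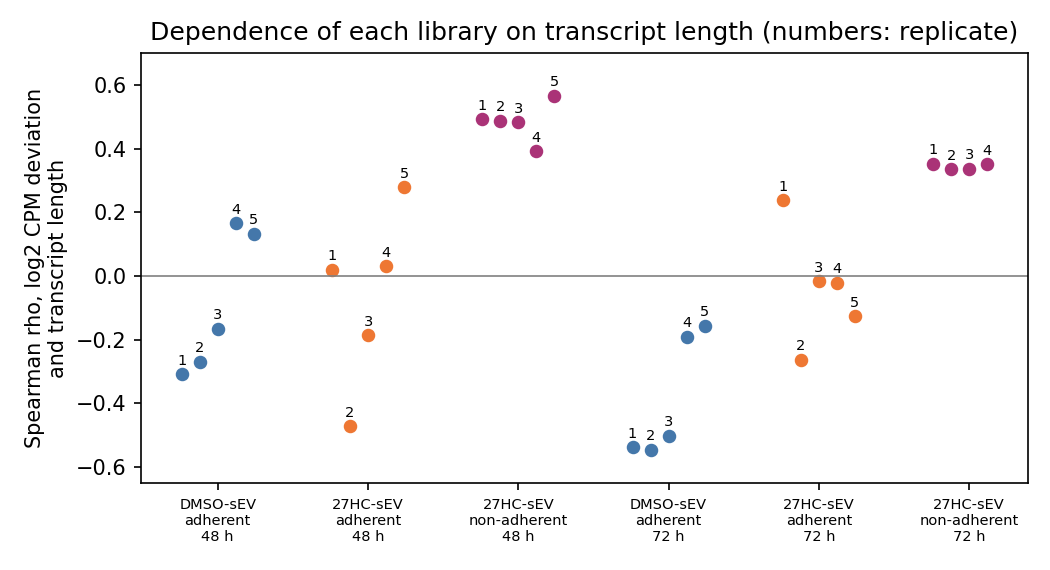
Spearman correlation, across genes, of each library's log2 CPM deviation with transcript length (y axis, unitless), by group (x axis), one point per library. The 5 non-adherent libraries at 48 h lie between 0.391 and 0.565 and the 4 at 72 h between 0.335 and 0.353, while DMSO-sEV libraries at 72 h lie between -0.545 and -0.157.

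Non-adherent 27HC-sEV cells against DMSO-sEV cells joins both steps. At 48 h 4313 genes rose and 4342 fell, and at 72 h 4980 rose and 4705 fell. The largest increases at 48 h were Gpnmb (11.1-fold), Dio2 (10.7-fold), Prl2c3 (9.13-fold) and Ube2ql1 (8.93-fold), and the largest decreases Idi1 (22.3-fold), Ccn2 (18-fold), Cyp51 (16.9-fold) and Fgfbp1 (15.7-fold). At 72 h Prl2c3 (28-fold), Dio2 (17.6-fold), Lcn2 (13.4-fold) and Gpnmb (9.3-fold) rose most, and Idi1 (37.1-fold), Fgfbp1 (23.2-fold), Cyp51 (22.4-fold) and Insig1 (15.8-fold) fell most. Cholesterol genes fell in 27 of 28 at 48 h (median -2.59, camera adjusted p = 1.44e-89) and in all 28 at 72 h (median -2.32, camera adjusted p = 4.06e-56). NF-kappa B genes rose in 32 of 38 at 48 h (median 0.95, camera adjusted p = 2.15e-15), and interferon-stimulated genes fell in 36 of 40 at 72 h (median -1.001, camera adjusted p = 1.8e-08). Of 39 lists 17 and 20 were called at 48 and 72 h, 6 and 4 of them with an estimated correlation. The interferon call at 72 h held with an estimated correlation (adjusted p = 0.0238) but not with offsets as well (0.129, median -0.891).

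Comparing 72 with 48 h within each kind of cell asks what changes with a further day. In DMSO-sEV cells 3621 genes rose and 3097 fell. Slfn2, Mmp3, Cxcl1 and Mmp13 rose most, by 1.86 (SE 0.166), 1.65 (SE 0.144), 1.57 (SE 0.133) and 1.57 (SE 0.192), and Nrp1, Celsr1, Thbs1 and Col12a1 fell most, by 1.59 (SE 0.117), 1.57 (SE 0.15), 1.51 (SE 0.13) and 1.47 (SE 0.181), with Celsr1 at -1 when offsets were used. There, interferon-stimulated genes rose in 28 of 40 (median 0.53, camera adjusted p = 1.56e-08, adjusted p = 0.0726 with an estimated correlation) and extracellular matrix genes fell in 24 of 31 (25 over the list alone, median -0.99, or -0.636 with offsets, camera adjusted p = 6.32e-16, adjusted p = 0.153 with an estimated correlation). Ribosomal protein genes rose in 37 of 40 (median 0.65, or 0.291 with offsets, camera adjusted p = 4.98e-10, adjusted p = 0.428 with an estimated correlation), beside a length trend of Spearman -0.43 across genes. In adherent 27HC-sEV cells 856 genes rose and 851 fell, with Lcn2 up 4.91-fold, Tgfbr3, Mmp3 and Gpnmb up by 1.32 (SE 0.128), 1.20 (SE 0.141) and 1.16 (SE 0.146), and Gbp3, Krt14, Oasl1 and Insig1 down by 1.43 (SE 0.108), 1.36 (SE 0.078), 1.25 (SE 0.101) and 1.13 (SE 0.093). There G2/M genes fell in 35 of 40 (40 over the list alone, median -0.36, camera adjusted p = 1.45e-54), interferon-stimulated genes in 24 of 40 (27 over the list alone, median -0.57, camera adjusted p = 7.22e-30) and cholesterol genes in 17 of 28 (20 over the list alone, median -0.38, camera adjusted p = 6.54e-21), calls that all held with an estimated correlation. In non-adherent cells 742 rose and 899 fell. Prl2c3, Mmp13, Cxcl5 and Lcn2 rose by 1.62 (SE 0.143), 1.57 (SE 0.178), 1.03 (SE 0.123) and 0.96 (SE 0.175), and C1qtnf1, Egr1, Prss22 and Mmp9 fell by 1.30 (SE 0.125), 1.21 (SE 0.1), 1.20 (SE 0.174) and 1.07 (SE 0.147). There ATF4 genes rose in 19 of 39 and fell in 1 (24 and 5 over the list alone, median 0.23, camera adjusted p = 5.99e-12, adjusted p = 0.0839 with an estimated correlation).

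The difference between times was tested directly. For 27HC-sEVs against DMSO-sEVs 4857 genes changed with time, 2068 upward and 2789 downward. Those named led by adjusted p among genes with a mean log2 CPM of at least 3, which leaves out Ifit1 (-2.62, adjusted p = 2.36e-11). Oasl1 (-2.19, SE 0.142, adjusted p = 2.36e-11), Ifih1 (-1.20, SE 0.095) and Apol9b (-1.33, SE 0.106), all induced by interferon, led downward, with reads of Apol9b possibly shared with its near-identical neighbour Apol9a. The phosphatase Ptprs (1.03, SE 0.084, adjusted p = 2.33e-09), Pcnx3 (1.12, SE 0.095) and the ribosome receptor Rrbp1 (1.37, SE 0.124) led upward, or 0.467, 0.53 and 0.99 with length and GC offsets. Interferon-stimulated genes moved down in 33 of 40 (34 over the list alone, median -1.01, camera adjusted p = 1.5e-27) and extracellular matrix genes up in 26 of 31 (27 over the list alone, median 1.24, or 0.655 with offsets, camera adjusted p = 2.87e-20, adjusted p = 0.0822 with an estimated correlation). For non-adherent against adherent cells 598 genes changed with time, 154 upward and 444 downward. Niban1 (0.79, SE 0.097, adjusted p = 2.76e-05), Fdps (0.73, SE 0.095) and Asns (0.60, SE 0.082) led upward, and Nptx1 (-1.35, SE 0.163), Dusp6 (-0.64, SE 0.077) and Ank (-0.74, SE 0.098) downward. ATF4 genes moved up in 19 of 39 and down in 0 (26 and 2 over the list alone, median 0.34, camera adjusted p = 6.55e-16, adjusted p = 0.054 with an estimated correlation, or 0.0239 with offsets as well). Across all tested genes, fold changes at 48 and 72 h correlated at Pearson 0.667 and Spearman 0.561 for adherent 27HC-sEV against DMSO-sEV cells, and at 0.658 and 0.751 for non-adherent against adherent cells. Genes are not independent replicates. In the former, 3956 of 4402 genes called at both times had the same direction and 446 the opposite.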

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

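The tests of differences between times and of libraries far from their group were planned, and the tests of the length trend, of DMSO subsets, of LXR targets and of neutrophil transcripts were chosen after their results were seen. Values of 1 library apart from its group were sought in 374 groups of values and found in 34 (9.09%), where chance gives about 1 in 20. Gene values in the paragraphs on single libraries are log2 CPM, with the median of the group's other libraries in brackets.

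Non-adherent cells at 48 h, replicate 4, stood below the other libraries in Lcn2 at 5.15 (6.02), Abcc3 at 4.35 (5.09), Hhip at 5.58 (6.23), Col5a1 at 5.05 (5.51), Serpine2 at 6.54 (6.99), Ltbp3 at 8.3 (8.72), Lgr6 at 5.64 (6.21), Itgb3 at 4.22 (4.65), Cdh1 at 8.38 (8.72), Epcam at 8.18 (8.43), Cd44 at 9.47 (9.82) and C1qtnf1 at 3.82 (4.4). Except for Cdh1 and Epcam these 12 genes rose in non-adherent against adherent cells at 48 h. Replicate 3 of that group was low in Ctsw at 2.31 (2.71). Non-adherent cells at 72 h, replicate 2, were low in Sox9 at 7.6 (7.7) and high in Rps6 at 5.44 (5.32) and Pdk1 at 6.16 (6.07), and replicate 4 was low in Idi1 at 4.33 (4.58).

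Adherent 27HC-sEV cells at 48 h, replicate 2, had 19.3 M reads (Dixon ratio 0.893), were high in Ctsw at 4.39 (4.17), Pgk1 at 10.34 (10.19) and Ldha at 10.8 (10.63), and low in Ptprs at 7.67 (7.86). Replicate 1 was high in Snai1 at 3.21 (2.9) and Hhip at 4.87 (4.28), and replicate 3 low in Rrm2 at 7.14 (7.19) and Ccn2 at 6.73 (6.93). At 72 h, replicate 4 was low in Cth at 3.49 (3.58). DMSO-sEV cells at 48 h were low in replicate 5 in Cdh1 at 8.25 (8.91), Thbs1 at 9.93 (10.26) and Pcnx3 at 5.45 (5.61), low in replicate 1 in Ccna2 at 8.79 (8.85) and high in replicate 3 in Mcm3 at 8.18 (8.11). At 72 h they were high in replicate 3 in Oasl1 at 4.52 (4.23) and in replicate 4 in Pcnx3 at 4.92 (4.69).

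By edgeR's test the 27HC-sEV effect differed between times in 38 of 52 named genes. The interferon-induced genes Ifit1 (-2.62) and Ifih1 (-1.2) shifted downward, and Lcn2 (2.17), Fn1 (1.35), Steap3 (1.34), Lama5 (1.3), Dio2 (1.19), Cdh1 (0.95), Lamb2 (0.88), Ccn2 (0.59), Slc6a9 (0.56), Cd44 (0.53), Hsd17b7 (0.52), Slc7a11 (0.49), Srm (0.29) and Vim (0.18) shifted upward, in log2 units. Sterol genes shifted down in Idi1 (-1.4), Insig1 (-1.24), Cyp51 (-0.82), Fdps (-0.63) and Hmgcs1 (-0.27). Stress and early-response genes shifted down in Atf3 (-1.01), Ddit3 (-0.96), Crebrf (-0.66), Trib3 (-0.63), Fam171b (-0.51), Ndrg1 (-0.51), Sqstm1 (-0.49), Dusp1 (-0.37), Nfkbia (-0.31), Traf1 (-0.3) and Mxi1 (-0.28). Growth genes shifted down in Ccnb1 (-0.55), Kif20a (-0.37), Atp5b (-0.33), Rrm1 (-0.3), Ccna2 (-0.23) and Rrm2 (-0.16).

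The adherence difference changed with time in 23 of 61 named genes (598 of all 13008). It shrank for the risers Abcc3 (-1.45), Nptx1 (-1.35), Lcn2 (-1.34), Hhip (-1.18), Lrp1 (-1.12), Ptges (-1.05), Lgr6 (-1.03), Serpine2 (-0.99), Csf3 (-0.98), Col5a1 (-0.93), Bmp7 (-0.85), Itgb3 (-0.84), Ltbp3 (-0.83), Lama5 (-0.76), Cd44 (-0.63), Glis3 (-0.62), Tnfaip2 (-0.51), Hmga1 (-0.34) and Vim (-0.22). It also shrank for the fallers Serpinb5 (0.66), Asns (0.6), Gadd45b (0.53) and Ddit4 (0.3). Naming by changes at 48 h favours this.

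The first pattern weighed is the trend of fold changes with transcript length and GC content. With offsets the real grouping and highest of 99 other splits called 6981 and 0 genes for adherent against DMSO-sEV cells at 72 h. For non-adherent against adherent cells they called 5916 and 1747 at 48 h and 4118 and 2608 at 72 h. A remaining trend that follows the groups could do the same, so this cannot decide. Offsets ended many calls: in 1 fit of all groups 6034 of 8187, 3943 of 6693 and 1802 of 3342 calls held in the same direction with offsets, and 6289, 4042 and 1802 in either. DMSO replicates 1 to 3 alone do not make the GC part at 72 h, since replicates 4 and 5 alone left a Spearman correlation of 0.214. Whether they make the length part stays open: replicates 4 and 5 alone left 0.108, against 0.456 with replicates 1 to 3, and single adherent libraries at 72 h spread by 0.184 (SD). In non-adherent cells at 48 h the ribosomal and oxidative phosphorylation medians were -0.306 and -0.233 with offsets. These argue against a trend in the length and GC of the longest transcript as their whole cause. A trend in the length of the transcripts expressed, which can be shorter, stays open. For the matrix list, with medians of 0.437 in adherent cells at 72 h and 0.301 in non-adherent cells at 48 h, the trend and a change of matrix genes cannot be told apart, because length goes with both, and RNA quality, which could differ between fractions, is not recorded in the labels.

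The second pattern is the lower expression of cholesterol biosynthesis genes. Its median at 48 h was -2.315 with length and GC offsets, and no higher than -2.088 with either subset of DMSO libraries, which argues against both as its whole cause. A candidate explanation is sterol carried with the vesicles, since 27HC was given to the neutrophils, and sterols lower this pathway. The LXR list, which sterol could raise, cannot tell (camera adjusted p = 0.468). Its low Abca1 and Abcg1 rose, while Scd1 and Scd2 fell. Other effects of the exposure on vesicle content stay open as untested.

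The third pattern is the higher neutrophil marker list in non-adherent cells at 48 h, for which neutrophil RNA carried with the vesicles is a candidate source. The abundant granule transcripts S100a8, S100a9, Ngp, Camp and Ltf together rose by 0.0565 CPM, from 0.296 to 0.352 CPM, while Lcn2 rose by 47 CPM, which argues against it. Of the list's genes 7 were tested, and Lcn2 also belongs to the NF-kappa B and luminal lists. Expression by the tumour cells themselves stays open as untested.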

How the results depend on the processing

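Length and GC offsets and both DMSO subsets were chosen after seeing the data, and the other alternatives were planned. Of 660 values of counts of genes, counts of lists and correlations under alternatives, 622 kept their direction and stayed within 1.5 times the reported count or within the replicate spread, and 38 did not. Of 4527 values of 203 named-gene results, 4474 kept direction and call, 23 lost the call, 14 gained it and 16 turned sign. Unrounded counts, RLE and upper-quartile factors, DESeq2, limma-voom, limma-trend and DMSO replicates 1 to 3 alone changed 0 of the counts and correlations. Except where a construction is named, the cause was not tested.

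Without a filter, which adds genes of few counts to the adjustment, 970 genes rose in non-adherent against adherent cells at 72 h and 516 fell with time in adherent cells. The correlations of fold changes between times then were 0.29 (Pearson) and 0.327 (Spearman) for adherent against DMSO-sEV cells, and 0.136 and 0.352 for non-adherent against adherent cells. That last Pearson value was 0.738 with 1 CPM required in every library of a group and 0.741 in fits of only the groups compared. Those fits, which take the spread from fewer libraries, gave 2923 genes lower in non-adherent cells at 72 h, 2279 higher with time in DMSO-sEV cells, 1619 higher and 1870 lower with time in non-adherent cells, and 1213 for the change of the adherence difference with time.

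With a replicate block 2738 genes were lower in non-adherent cells at 72 h and 933 changed with adherence and time. Libraries of the same number did not all deviate together: their residuals correlated between -0.103 and 0.368, with the highest in DMSO-sEV cells between times, where 4 of 5 pairs were over 0.1 and 3 of 5 libraries matched best with their own number. The block was used only here, and moved the counts of that comparison by less than 1.5 times.

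With DMSO replicates 4 and 5 alone, which leave 2 libraries per group, 1598 genes rose and 1752 fell with time in DMSO-sEV cells and 3061 changed with treatment and time. In that subset the log2 fold changes of adherent against DMSO-sEV cells turned for Epcam at 48 h to 0.309 (adjusted p = 0.0218, with a range of 0.0218 to 0.997 over all alternatives), Zeb2 at 48 h to -0.122, Cd44 at 48 h to 0.202, Epcam at 72 h to 0.389 (adjusted p = 0.00366, with a range of 3.39e-05 to 0.89) and Vim at 72 h to -0.007. With DMSO replicates 1 to 3 alone Epcam was called in the opposite direction, at -0.212 (adjusted p = 0.0241) and -0.413 (adjusted p = 3.39e-05), and Zeb2 at 48 h was called at 0.24 (adjusted p = 0.00106, with a range of 0.00106 to 0.905). With length and GC offsets 1396 genes fell with time in adherent cells, 17 lists were called in non-adherent cells at 72 h, and the correlations between times were 0.734 (Pearson, adherent against DMSO-sEV) and 0.635 (Spearman, non-adherent against adherent). With an estimated correlation 9, 5, 0 and 0 lists were called for adherent against DMSO-sEV cells at 48 and 72 h and non-adherent against adherent cells at 48 and 72 h. Fry called 34 lists in adherent cells at 72 h and 17 in non-adherent cells at 72 h, since it does not compare a list with other genes.

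Leaving out 1 library at a time, genes higher in non-adherent cells at 72 h ran from 1125 to 1979 and genes lower from 910 to 1929. Low counts came without adherent replicate 2 or non-adherent replicate 1, 3 or, for genes lower, 4. Genes higher with time in non-adherent cells ran from 480 to 846, with 492 and 480 without replicate 1 or 3 at 72 h. Genes changing with adherence and time ran from 350, without non-adherent replicate 1 at 72 h, to 853. Signs turned for values near 0: at 48 h in adherent cells Epcam ran from -0.126 to 0.057, Fn1 from -0.181 to 0.021 and Cd44 from -0.121 to 0.017, and in non-adherent cells at 72 h Snai1 ran from -0.068 to 0.108 and Zeb1 from -0.328 to 0.016. The Cdh1 call at 48 h was lost without any of DMSO-sEV replicates 1 to 4 or adherent replicates 2 to 5.

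Removing mitochondrially encoded genes was not run, since the table holds 0 of them, nor was putting back replicate 5 of the non-adherent cells at 72 h, which has no column. Depth limits genes such as Zeb1 and Abca1, at 0.679 CPM (SD 0.217, n = 4) and 1.21 CPM (SD 0.316, n = 4) in non-adherent cells at 72 h.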

Other observations

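The counts of splits below were planned, and the correlation between the treatment and adherence changes and the genes named here were chosen after their values were seen. Several members moved far in lists whose medians stayed small. The Wnt antagonist Notum rose in adherent against DMSO-sEV cells by 1.02 log2 units at 48 h and 3.24 at 72 h, and Abcg2, an efflux transporter used as a stem cell marker, fell by 1.28 and 1.81 and again in non-adherent cells by 1.31 and 0.95. The tight junction gene Cldn1 rose in attached cells by 2.49 at 72 h and fell in non-adherent cells by 1.49. Mmp9 fell in attached cells by 2.12 at 48 h and 2.37 at 72 h while Mmp3 rose by 0.92 and 0.47. Itga1 rose by 2.04 in non-adherent cells at 48 h, where Itgb6 fell by 1.45.

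Fold changes of adherent against DMSO-sEV cells and of non-adherent against adherent cells share the adherent libraries. Their correlation across 10922 genes was 0.066 at 48 h and 0.443 at 72 h. With the adherent libraries divided between both sides, in 20 splits, it ran from -0.011 to 0.176 at 48 h and from 0.325 to 0.556 at 72 h. With length and GC offsets, over 10637 genes, the split values ran from 0.054 to 0.152 and from 0.176 to 0.383.

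DMSO-sEV libraries fell into replicates 1 to 3 and replicates 4 and 5. Residuals correlated at -0.487 to -0.312 across that boundary at 48 h and -0.633 to -0.338 at 72 h, and at -0.107 to 0.12 and -0.075 to 0.417 within it. The labels name no batch. Called genes numbered 6953 and 5668 with replicates 1 to 3 or 4 and 5 alone for adherent against DMSO-sEV cells at 48 h, and 9362 and 7137 at 72 h, with Spearman correlations with length of 0.191 and -0.178, and 0.456 and 0.108.

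The libraries were divided in 100 splits, each fitted to only the groups compared. Splits were drawn from 126 for pairs of groups, and within each kind of cell for differences between times. In 10 results the real grouping called more genes than any other split drawn (1 split of 100 as large each), under the planned limit of 5 of 100. Such splits cannot tell the conditions from a technical difference that follows the groups. The real and highest other counts were 5557 and 463 for adherent against DMSO-sEV cells at 48 h, 7199 and 0 at 72 h, 7534 and 2392 for non-adherent against adherent cells at 48 h, 5728 and 4914 at 72 h, 8500 and 0 for non-adherent against DMSO-sEV cells at 48 h and 8663 and 7394 at 72 h. With time they were 4492 and 3854 in DMSO-sEV cells, 2064 and 566 in adherent and 3489 and 1642 in non-adherent cells, and 4112 and 3137 for the change of the treatment effect with time. For the change of the adherence difference with time 2 of 100 splits were as large, with 1213 genes and 2572 in the highest other. Why another split called more was not tested. For counts of lists, adherent against DMSO-sEV cells at 48 h came narrowly under the planned limit of 5 of 100 (4 of 100 splits, 21 lists and 25 in the highest other). Chance cannot be excluded at 72 h (23 of 100, 19 and 27), nor for non-adherent against adherent cells at 48 h (5 of 100, 23 and 26) or 72 h (40 of 100, 12 and 22). The median other split called 14, 14, 12 and 10 lists in this order, and 0 genes.

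The authors' deposited table marks 11637 genes in an analysis of variance column and others in a column for 72 against 48 h, without saying how. Of 12031 genes called here in any pair of groups 11528 carry the former mark, and of 7831 called in any comparison of times 7357 carry the latter.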
